A study of Mus musculus with 12 samples.

How the data were processed

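The series held 12 Illumina BeadChip arrays of mouse C2C12 myoblasts in 6 groups of 2: wild-type cells in growth medium (GM), wild-type cells in differentiation medium (DM), and cells in differentiation medium after transfection with siRNA against a scrambled sequence (siScramble), BRG1 (siBRG1), BAF60b (siBAF60b) or BAF60c (siBAF60c). Per the labels, siRNA pools were given in growth medium with 15% serum, cells were shifted to ITS differentiation medium 36 h later, and total RNA was taken after a further 18 h, with 500 ng labelled as Cy3 cRNA. The same protocol text stood beside every sample, and the wild-type samples carried the transfection entry "control", so whether they received a transfection reagent is not given in the sources used here. Each label gave 1 of 2 replicate numbers. Nothing in the labels says that the 2 replicates were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical.

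The array identifiers placed the samples on 3 BeadChips. The first carried replicate 1 of all 4 transfected groups, the second replicate 1 of GM and DM and replicate 2 of siScramble, siBAF60b and siBAF60c, and the third replicate 2 of GM, DM and siBRG1. The growth and differentiation medium groups were balanced over their 2 chips, whereas siBRG1 shared only the first chip with siScramble.

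The deposited scanner table held a linear signal intensity and a detection p-value for 45281 probes on each array, per the file headers. The deposited processed table held 23165 of those probes as linear intensity. Its columns shared their quantiles, with a median of 164, and its ranks on every array equalled those of the scanner table (Spearman correlation 1), so the authors' values were quantile normalized. None of the 22116 probes left out by the authors was detected on any of the 12 arrays at a detection p under 0.05. The scale and the direction of the authors' values were therefore known. Their software, version and background setting were not given in the sources used here, nor was whether other arrays were normalized with these 12.

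The scanner table was the starting point. Median signal per array ran from 119 to 149 and mean signal from 335 (siBAF60c replicate 1) to 839 (GM replicate 1), and between 12724 (28.1%, DM replicate 2) and 15414 (34.0%, GM replicate 1) of the probes were detected at p under 0.05. Intensities were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values and an offset of 16. Probes detected at p under 0.05 on at least 2 arrays were kept, which left 17565. Probe names came from a supplied table: 19589 probes of the processed table were named by 1 gene, 8 by several and 3568 by none. For genes with several kept probes (3438) the probe with the highest mean was used and the others were given beside it where they differed. This left 10346 genes, while 2439 kept probes without a single name were analysed apart. Correlation between the 2 arrays of a group was 0.945 in DM and between 0.979 and 0.988 in the other 5 groups. The arrays of DM differed by more than 1 on the log2 scale in 1836 genes, against 108 to 462 in the other groups.

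All 12 arrays and 6 groups were fitted together with lmFit and eBayes of limma, with 6 residual and 8.17 prior degrees of freedom. Contrasts were taken between groups, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 across all genes of a comparison. Every adjusted p of a gene in the text is from this limma fit unless another setting is named. Values are log2 differences with their standard error (SE), from 2 arrays per group. The median SE of a difference was 0.31, and 517 genes were expected under an unadjusted p of 0.05 by chance. The spread behind each p is pooled over all 6 groups and includes that of the DM arrays, the widest. In comparisons without DM, chance alone may therefore give fewer than 517. With 2 arrays per group the smallest exact p of a permutation is 0.333, and 33.3% of genes are expected to have non-overlapping arrays by chance. Where every probe of a gene lay below detection on both arrays of the dimmer group, the change is given as at least the fold above the lowest value of a detected probe on those arrays (5.20 to 5.53 on the log2 scale). Detection on only 1 of the 2 arrays of the dimmer group is stated beside the value.

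For the 3 siRNA targets the p-value was also adjusted over those 3 tests. A total of 26 gene lists on muscle structure and function, myogenic regulation, the cell cycle, serum response, stress, signalling and other cell types were written from general knowledge. They were tested with camera of limma at a preset inter-gene correlation of 0.01, with the p-value adjusted over the 26 lists of a comparison. An estimated correlation and fry were run beside it. The members of a list were also adjusted over the list alone. Genes that differed between DM and GM by at least 1 on the log2 scale (884 higher, 781 lower) were followed as sets in the knockdowns. The differences that define these sets come from wild-type arrays only, while the spread used to call them came from all 6 groups. The p-values of the sets were adjusted over 12 tests (2 sets in 6 comparisons). Knockdown comparisons against siScramble share their control, and siScramble has only 2 arrays, so the control could not be split. The overlap expected from the sharing alone was taken from 50 simulated data sets without effects.

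Genes are named in the text by a fixed rule. They are the 3 targets with Smarca2, the genes Myod1, Myog, Mef2c, Ckm, Tnnt3, Chrna1, Cdkn1a and Ccnd1, the largest passing changes whose arrays did not overlap (8 per direction against GM or siScramble, 4 per direction in the other comparisons), and members of lists with the smallest p. The Smarcd1 probe was not detected on any array and was not kept, and Myh3 was named by no probe. The groups, the comparisons, the lists, the naming rule and the alternatives were fixed before the data were examined, apart from a fit of the 8 transfected arrays alone, which was chosen after seeing the data. The alternatives were no background correction, median scaling, the authors' processed values, no filter or a stricter one (detection p under 0.01), every kept probe or the mean of probes, the replicate number as a block, the BeadChip as a fixed or random block, a trended robust variance, array weights, a minimum change of 1, the estimated correlation for lists, DM as the control, only the groups compared, and each array left out in turn.

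The procedure was tested on simulated data with the same groups. Values were drawn independently between genes, with 1 pooled spread per gene for all groups. On the real arrays the standard deviation from the group mean was 0.39 in DM and 0.18 to 0.24 in the other groups. The rates below may therefore differ from those of the real comparisons. Changes of 1 on the log2 scale were recovered in 16.4% to 40.3% of planted genes by comparison, changes of 2 in 92.5% to 100%, and changes of 3 in 100%, with 4 to 18 false calls among 10346 genes. The number of arrays therefore limits precision, and a change of 2-fold or less that is absent from the calls is not shown to be absent from the cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.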

Results

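Each siRNA lowered the transcript of its own target. Smarcd2, which encodes BAF60b, stood at 34.1% of siScramble in siBAF60b cells (log2 difference -1.55, 95% confidence interval -2.39 to -0.72, 2 arrays per group). Smarca4, which encodes the ATPase BRG1, stood at 52.95% in siBRG1 cells (-0.92, -1.71 to -0.12). Smarcd3, which encodes BAF60c, stood at 52.3% in siBAF60c cells (-0.94, -1.68 to -0.20). The arrays did not overlap in any of the 3 cases, and the adjusted p over the 3 targets was 0.00394 for Smarcd2, 0.0266 for Smarca4 and 0.0253 for Smarcd3. Adjusted over all genes none passed (0.679, 0.515 and 0.858). Array by array, Smarca4 was 7.77 and 7.20 in siScramble, 6.77 and 6.38 in siBRG1, 7.78 and 6.84 in siBAF60b, 7.53 and 6.97 in siBAF60c, 7.74 and 7.59 in GM, and 8.02 and 8.79 in DM. Smarcd2 was 9.83 and 9.71 in siScramble, 8.10 and 8.34 in siBAF60b, 10.09 and 9.49 in siBRG1, 9.75 and 9.53 in siBAF60c, 10.29 and 9.24 in GM, and 9.67 and 10.74 in DM. Smarcd3 was 9.10 and 8.51 in siScramble, 8.18 and 7.56 in siBAF60c, 8.23 and 8.24 in siBRG1, 8.47 and 8.57 in siBAF60b, 7.93 and 7.91 in GM, and 8.71 and 9.74 in DM. Smarcd3 thus also stood 0.57 lower in siBRG1 than in siScramble without passing (log2 difference -0.57, SE 0.35, adjusted p = 0.769). The other subunits were nearer to siScramble. In siBRG1 Smarcd2 differed by 0.02 and the second ATPase Smarca2 by 0.15. A second, dim Smarca2 probe read 6.265 and 4.70 in siScramble, detected on replicate 1 only, and 4.93 and 5.02 in siBRG1, not detected. That probe read 5.625 and 5.73 in siBAF60b and, not detected, 5.13 and 5.07 in siBAF60c. The differences in siBAF60b were -0.18 for Smarca4, -0.28 for Smarcd3 and -0.01 for Smarca2, and those in siBAF60c -0.23 for Smarca4, -0.13 for Smarcd2 and 0.11 for Smarca2.

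**Figure D1:**
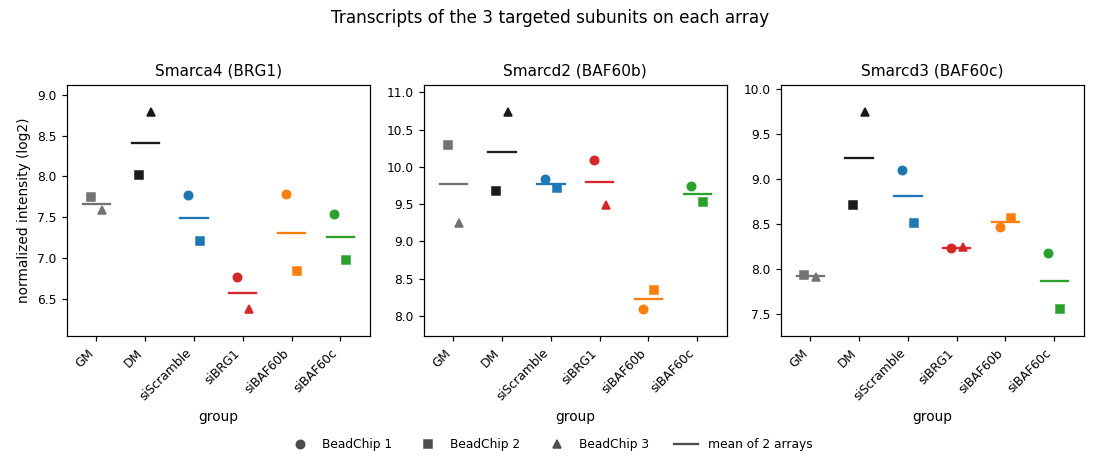
Each point is 1 array and each line the mean of 2 arrays; Smarcd2 stood at 34.1% of siScramble in siBAF60b, Smarca4 at 52.95% in siBRG1 and Smarcd3 at 52.3% in siBAF60c. Marker shape gives the BeadChip.

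In wild-type cells, the cardiac actin gene Actc1 rose by 7.69 on the log2 scale in DM against GM (SE 0.42, adjusted p = 8.52e-08, 2 arrays per group). The myogenic regulator Myog rose by 6.67 (SE 0.52), the cell cycle inhibitor Cdkn1c by 6.59 (SE 0.32), and the troponin gene Tnnt3 by 5.66 (SE 0.37). Creatine kinase Ckm rose at least 28.4-fold and the hormone gene Stc1 at least 35.4-fold from below detection. Hrc (6.31, SE 0.46) and the calcium pump gene Atp2a1 (6.05, SE 0.47) of the sarcoplasmic reticulum and the ubiquitin ligase subunit Asb2 (5.89, SE 0.33) also rose. Myog, Tnnt3, Hrc and Asb2 were each detected on 1 of the 2 GM arrays, and a second Myog probe differed by only 1.08 without passing (adjusted p = 0.231). The cell cycle inhibitor Cdkn1a rose by 2.73 (SE 0.28, adjusted p = 1.18e-05), the acetylcholine receptor subunit Chrna1 by 1.27 (SE 0.31, adjusted p = 0.0106) and Smarcd3 by 1.31 (SE 0.35, adjusted p = 0.0162). The D-type cyclin Ccnd1 fell by 2.99 (SE 0.27, adjusted p = 2.99e-06). Among the largest falls were those of the prolactin-family genes Prl2c2 (at least 23.7-fold), Prl2c3 (at least 26.8-fold) and Prl2c4 (-4.02, SE 0.46, detected on 1 DM array). The membrane protein Sema7a (-4.83, SE 0.31), the matrix-signalling gene Ccn2 (-4.58, SE 0.28), Lce1g (at least 9.11-fold), the kinase Prkg2 (-4.15, SE 0.44) and the calcification inhibitor Mgp (-3.95, SE 0.43) also fell. Myod1 itself (-0.48, SE 0.37, adjusted p = 0.404), Mef2c (0.48, adjusted p = 0.254), Smarca4 (0.74, adjusted p = 0.185), Smarcd2 (0.44, adjusted p = 0.472) and Smarca2 (0.55, adjusted p = 0.151) did not pass. In all, limma called 2010 of 10346 genes, 1086 higher and 924 lower. Arrays did not overlap in 5488 genes, where chance alone gives 33.3%. Within the 2 BeadChips that held both groups Actc1 differed by 7.53 and 7.85, Ccnd1 by -3.02 and -2.96, Chrna1 by 1.16 and 1.37, and Smarcd3 by 0.78 and 1.84. With median scaling the all-gene median shifted by -0.48, and the 1369 genes then called were 199 higher and 1170 lower, so the balance between the directions rests on quantile normalization. The count also rested on single arrays, with 3447 genes without DM replicate 1 and 920 without GM replicate 2. Neither Smarcd3 nor Chrna1 passed without DM replicate 2 (0.79, adjusted p = 0.138, and 0.94, adjusted p = 0.0748), without GM replicate 1 (adjusted p = 0.0752 and 0.0983) or with median scaling (0.54 and 0.43). Array weights and a fit of only the groups compared also ended both calls, and Smarcd3 did not pass without GM replicate 2 (adjusted p = 0.0962).

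Of the 26 gene lists, 11 passed between DM and GM, and none did with an estimated correlation, for which the second p is given below. Sarcomere genes had a median of 2.62 (28 of 39 rose and 1 fell, adjusted p = 6.59e-19; adjusted p = 0.0545 with an estimated correlation). The thick-filament chaperone Unc45b rose at least 29.99-fold, and the sarcomere protein Klhl41 by 5.42 from detection on 1 GM array. Excitation-contraction coupling genes had a median of 1.57 (10 of 18 rose, 12 rose and 1 fell adjusted over the list alone, adjusted p = 3.33e-07; 0.0545 with an estimated correlation), among them the calcium channel Ryr1 (4.23, SE 0.36). Acetylcholine receptor and neuromuscular junction genes had a median of 1.08 (5 of 9 rose, adjusted p = 0.0144; 0.0727 with an estimated correlation), led by the fetal subunit Chrng (3.71, SE 0.37). The dystrophin complex had 0.93 (4 of 8 rose and 1 fell, 5 and 1 over the list alone, adjusted p = 0.0255, and 0.133 with an estimated correlation). It was led by Dtna (2.68, SE 0.37) and by Dag1 (2.20, SE 0.31), which links the membrane to the matrix. Muscle energy metabolism had 1.42 (9 of 16 rose and 1 fell, adjusted p = 2.32e-05; 0.0545 with an estimated correlation), with myoglobin Mb at 5.39 (SE 0.31). Cholesterol biosynthesis had 1.10 (11 of 18 rose and 1 fell, adjusted p = 6.97e-05; 0.0545 with an estimated correlation), with the mevalonate enzymes Mvd (2.33, SE 0.25) and Fdps (1.89, SE 0.29).

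DNA replication genes had a median of -1.51 between DM and GM (28 of 32 fell and 1 rose, 30 and 1 over the list alone, adjusted p = 4.18e-18; 0.0545 with an estimated correlation), among them thymidine kinase Tk1 (-2.24, SE 0.28) and the licensing factor Cdt1 (-1.98, SE 0.25). Mitosis genes had -1.30 (17 of 26 fell, 22 over the list alone, adjusted p = 3.63e-13; 0.0545 with an estimated correlation), among them the mitotic kinase Cdk1 (-2.55, SE 0.39) and the checkpoint gene Mad2l1 (-2.44, SE 0.36). Serum-response immediate early genes had -1.26 (14 of 24 fell, 15 over the list alone, adjusted p = 3.86e-08; 0.0545 with an estimated correlation), with Phlda1, a growth factor-induced gene, at -3.08 (SE 0.26). SRF and smooth muscle contractile genes had -0.81 (7 of 17 fell and 1 rose, 9 and 1 over the list alone, adjusted p = 2.61e-04; 0.0545 with an estimated correlation), with the smooth muscle actin Actg2 at -3.08 (SE 0.30). TGF-beta and BMP targets had -0.49 (7 of 19 fell and 1 rose, 7 and 2 over the list alone, adjusted p = 0.0024; 0.0545 with an estimated correlation), with the bone morphogenetic protein antagonist Grem1 down at least 6.60-fold. The size of the list medians depended on background correction, without which sarcomere stood at 1.44, excitation-contraction coupling at 0.72 and SRF targets at -0.29.

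The remaining 15 lists did not pass between DM and GM, although several held strong single changes. Among inhibitors of myogenesis 6 of 23 rose and 6 fell (median -0.36, adjusted p = 0.614), the fallers including Id1 (-3.60, SE 0.31) and Id2 (-3.32, SE 0.25), which sequester MyoD partners, and the risers the Notch target Hey1 (3.09, SE 0.27). Among fusion genes 5 of 17 rose and 1 fell (0.40, adjusted p = 0.0751), with the fusion protein Mymk at 4.45 (SE 0.46). Cell cycle exit genes had a median of 0.70 (5 of 13 rose and 2 fell, adjusted p = 0.06), with Rb1 at 2.45 (SE 0.28). Myogenic regulators had 0.31 (3 of 8 rose, adjusted p = 0.297) and the BAF complex 0.26 (3 of 22 rose and 1 fell, adjusted p = 0.368). Extracellular matrix had 0.36 (10 of 31 rose and 5 fell, adjusted p = 0.614), IGF signalling 0.17 (5 of 18 rose and 2 fell, adjusted p = 0.295) and p53 targets 0.07 (5 of 19 rose and 3 fell, adjusted p = 0.578). The unfolded protein response had -0.18 (1 of 22 rose and 2 fell, adjusted p = 0.147), NF-kB targets -0.24 (1 of 15 rose and 4 fell, adjusted p = 0.0751) and interferon response genes 0.11 (3 of 19 rose and 1 fell, adjusted p = 0.614). Markers of other cell types were near 0. Adipocyte markers had 0.22 with a mean of -0.19 (1 of 9 rose and 2 fell, adjusted p = 0.493). Osteoblast and chondrocyte markers had 0.00 (1 of 8 rose, adjusted p = 0.871), macrophage and endothelial 0.08 (0 of 5 changed, adjusted p = 0.871) and neuronal -0.26 (1 of 9 fell, adjusted p = 0.639).

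**Figure D2:**
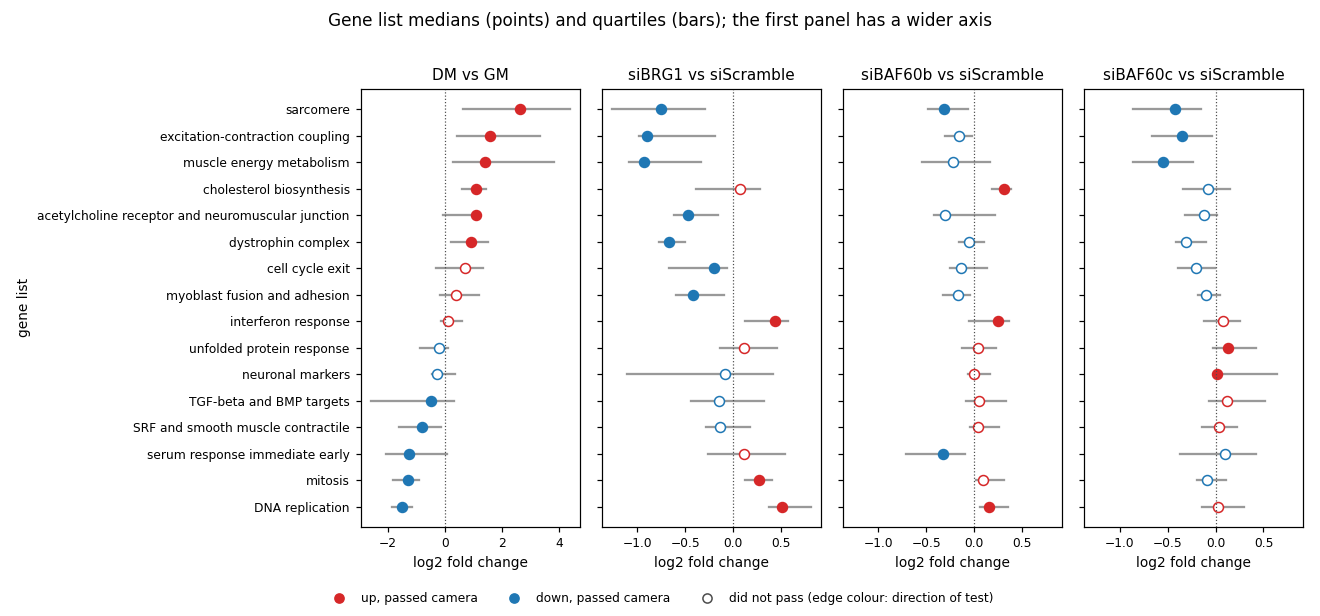
Points are list medians and bars the quartiles of the members; sarcomere genes had a median of 2.62 in DM against GM and -0.76, -0.31 and -0.42 in siBRG1, siBAF60b and siBAF60c against siScramble. Filled points passed camera at the preset correlation, and 0 lists passed with an estimated correlation.

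The glutathione transferase gene Gsta1 fell by 3.37 on the log2 scale in siBRG1 against siScramble (SE 0.33, adjusted p = 6.17e-04, 2 arrays per group; 2 further probes -3.41 and -2.84). Gsta2 fell by 2.80 (SE 0.46), and the prolactin-family genes Prl2c2, Prl2c3 and Prl2c4 fell by 2.9999 (SE 0.44), 2.77 (SE 0.45) and 2.55 (SE 0.46). These families are close paralogs whose probes may read more than 1 member. The surface antigen Ly6c1 (-2.89, SE 0.51), the FOXO-responsive gene Depp1 (-2.38, SE 0.30, adjusted p = 0.00598) and the muscle gene Klhl30 (-2.03, SE 0.31) also fell. The galectin-binding protein Lgals3bp (2.32, SE 0.42, detected on 1 siScramble array), alpha-globin Hba-a1 (2.06, SE 0.27, adjusted p = 0.00796), Sema7a (2.00, SE 0.31) and the lipid receptor Lpar4 (1.45, SE 0.27) rose. So did the D-type cyclin Ccnd2 (1.55, SE 0.29, detected on 1 siScramble array; second probe 0.49) and the replication licensing factor Cdc6 (1.43, SE 0.26, adjusted p = 0.0426). Lce1f (at least 3.06-fold), the neurofilament gene Nefm (at least 2.55-fold; a second probe 1.06, adjusted p = 0.528) and the retinoid carrier Crabp1 (at least 2.13-fold) rose from below detection. The differentiation genes stood lower without passing singly. The values were -1.50 for Ckm (SE 0.43, adjusted p = 0.231), -1.34 for Tnnt3 (SE 0.37, adjusted p = 0.207) and -1.12 for Myog (SE 0.52, adjusted p = 0.609). Cdkn1a stood at -0.74 (SE 0.28, adjusted p = 0.459), Chrna1 at -0.68 (SE 0.31, adjusted p = 0.593), Myod1 at -0.49 (SE 0.37, adjusted p = 0.841), Mef2c at 0.27 and Ccnd1 at 0.14. In all 29 genes passed (11 higher, 18 lower), 835 had an unadjusted p under 0.05 against 517 by chance, and 42.3% had non-overlapping arrays against 33.3% by chance. Within the first BeadChip Gsta1 differed by -3.13, Prl2c2 by -2.89 and Hba-a1 by 1.87, and 25 genes passed with the BeadChip as a fixed block. Ly6c1 (-2.40, adjusted p = 0.0798), Lce1f (adjusted p = 0.101), Crabp1 (adjusted p = 0.0598) and Ccnd2 (adjusted p = 0.0566) did not pass with that block. With the authors' values the rises were smaller and did not pass for Sema7a, Lgals3bp (1.05), Nefm (0.73), Lce1f (0.85), Crabp1 (0.60) and Ccnd2 (0.58), nor did Prl2c4 (-2.23), and the same 7 genes did not pass without background correction. The count fell to 1 without siScramble replicate 1 or siBRG1 replicate 2 and to 0 with median scaling, which shifted the all-gene median by 0.32. Against DM instead of siScramble 700 genes passed, and Gsta1, Gsta2 and the 3 Prl2c genes were then higher in siBRG1, at 2.02, 2.60, 3.95, 3.93 and 3.17. Ly6c1 (1.41, adjusted p = 0.117) and Depp1 (0.78, adjusted p = 0.136) also stood higher than in DM, without passing.

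**Figure D3:**
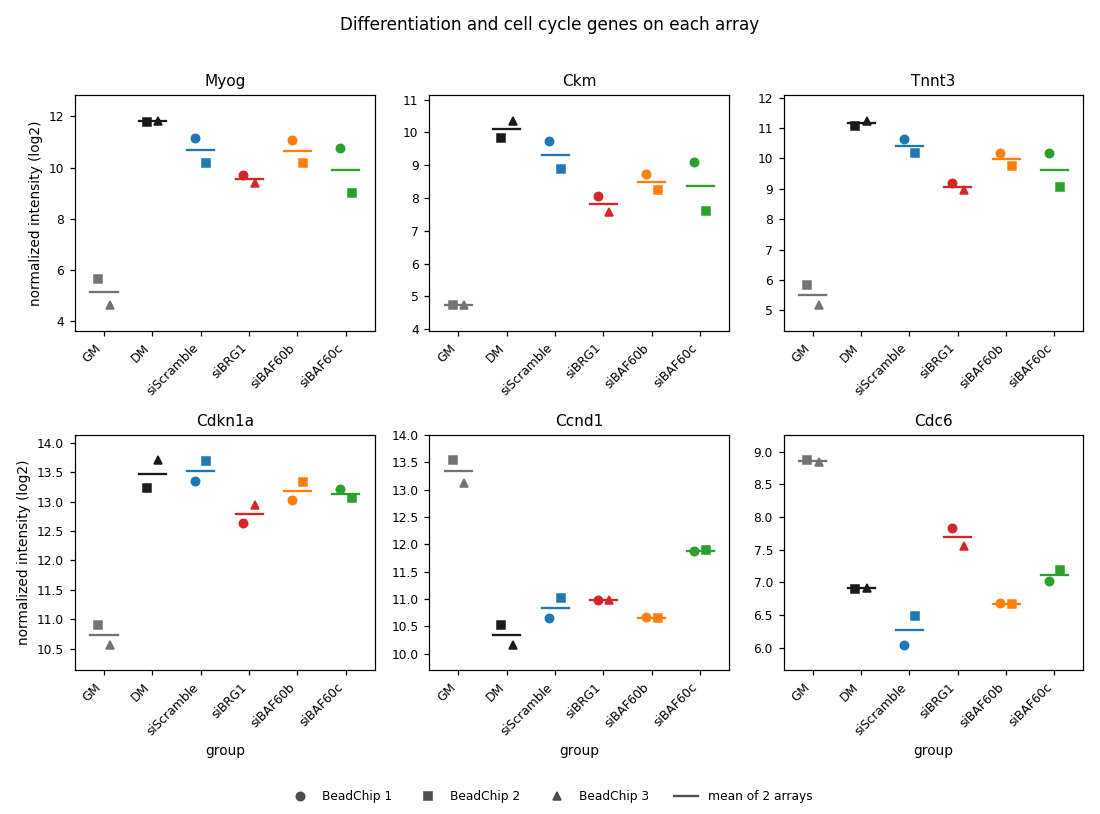
Each point is 1 array; Ckm differed by -1.50, Tnnt3 by -1.34, Cdkn1a by -0.74 and Cdc6 by 1.43 in siBRG1 against siScramble, of which only Cdc6 passed (adjusted p = 0.0426). Lines are means of 2 arrays.

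Across gene lists, siBRG1 cells expressed less of the contractile apparatus and more of the replication machinery than siScramble cells. Sarcomere genes had a median of -0.76 (36 of 39 below 0, 10 fell over the list alone, adjusted p = 1.00e-14; 0.0888 with an estimated correlation). The M-band gene Myom3 (-1.79, SE 0.37, adjusted p = 0.066) and skeletal actin Acta1 (-1.37, SE 0.34, adjusted p = 0.143) among them did not pass singly. Excitation-contraction coupling had -0.90 (16 of 18 below 0, 4 fell over the list alone, adjusted p = 4.28e-07; 0.0825 with an estimated correlation). Muscle energy metabolism had -0.93 (14 of 16 below 0, 7 fell and 1 rose over the list alone, adjusted p = 2.90e-06; 0.0757 with an estimated correlation). The dystrophin complex had -0.67 (7 of 8 below 0, 2 fell over the list alone, adjusted p = 4.85e-05; 0.0625 with an estimated correlation), with alpha-sarcoglycan Sgca at -1.31 (SE 0.26, adjusted p = 0.0544). Neuromuscular junction genes had -0.47 (adjusted p = 0.0147; 0.0888 with an estimated correlation). Fusion genes had -0.42 (adjusted p = 3.35e-04; 0.0825 with an estimated correlation) and cell cycle exit genes -0.20 (adjusted p = 0.0111; 0.0825 with an estimated correlation). DNA replication genes had a median of 0.51, with all 32 above 0 and 9 up over the list alone (adjusted p = 1.31e-13; 0.0625 with an estimated correlation), among them Cdt1 (1.25, SE 0.25, adjusted p = 0.0625). Mitosis genes had 0.27 (25 of 26 above 0, adjusted p = 0.00594; 0.456 with an estimated correlation). Interferon response genes had 0.44 (15 of 19 above 0, adjusted p = 3.35e-04; 0.0625 with an estimated correlation), with the antiviral gene Ifit3 at least 1.83-fold higher without passing (adjusted p = 0.107). With the BeadChip as a fixed block the medians were -0.81 for sarcomere, -0.84 for excitation-contraction coupling, -0.71 for energy metabolism and 0.59 for DNA replication. Within the first chip they were -0.93, -1.003, -0.96 and 0.56. Without background correction the medians were smaller, at -0.47, -0.46, -0.38 and 0.35, and interferon response stood at 0.14. With median scaling the cell cycle exit median turned to 0.24, below the all-gene median of 0.32.

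With the fit as reported, the genes induced by differentiation had a median below siScramble in all 3 knockdowns, lowest in siBRG1. Their median was -0.24 in siBRG1 (636 of 884 genes below 0, adjusted p = 6.74e-11 by camera), -0.12 in siBAF60c (574 below 0, adjusted p = 3.26e-05) and -0.07 in siBAF60b (539 below 0, adjusted p = 0.0329). Array medians relative to the siScramble mean were 0.052 and -0.052 in siScramble itself and -0.217 and -0.262 in siBRG1. They were -0.059 and -0.174 in siBAF60c and -0.037 and -0.103 in siBAF60b, so siBAF60b overlapped siScramble. With an estimated correlation the adjusted p was 0.513, 0.513 and 0.672 in siBRG1, siBAF60c and siBAF60b. With fry the p, not adjusted, was 0.14, 0.362 and 0.664 in the same order. Genes repressed by differentiation stood at 0.27, 0.09 and 0.12. Across 10346 genes the knockdown change correlated with the DM change at r -0.32 in siBRG1, -0.19 in siBAF60c and -0.14 in siBAF60b. The induced set stood 0.18 higher in siBAF60b than in siBRG1 (adjusted p = 4.92e-08; 0.513 with an estimated correlation) and 0.12 higher in siBAF60c than in siBRG1 (adjusted p = 0.00192; 0.618 with an estimated correlation). Between siBAF60c and siBAF60b it differed by -0.06 (adjusted p = 0.0225; 0.672 with an estimated correlation). The siBRG1 value was -0.12 without DM replicate 1. That array is not part of the siBRG1 comparison, but the fit without it draws its own set of genes. The size therefore depended on which genes made up the set, and the original set was not retested there. The siBAF60c value was -0.06 and did not pass without siBAF60c replicate 2. In siBAF60b the set did not pass without siScramble replicate 1 (-0.03), siBAF60b replicate 2 (-0.04), GM replicate 2 (-0.06) or DM replicate 2 (-0.06). With median scaling it stood at 0.03, below an all-gene median of 0.17.

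In siBAF60b cells 1 gene fell, Gsta1 (-2.45 on the log2 scale in siBAF60b against siScramble, SE 0.33, adjusted p = 0.0285, 2 arrays per group; 2 further probes -2.74 and -2.15), a gene of glutathione conjugation. The differentiation genes did not pass, with Myog at -0.03, Tnnt3 at -0.45, Cdkn1a at -0.34, Chrna1 at -0.38, Ccnd1 at -0.18, Myod1 at 0.36 and Ckm at -0.83 (SE 0.43), adjusted p = 0.999 for each. Mef2c stood at -0.38 (adjusted p = 0.999) but was below detection in siBAF60b, so the size of its difference was not measured. Serum-response immediate early genes were lower (median -0.33, 20 of 24 below 0, 3 fell over the list alone, adjusted p = 1.55e-08; 0.14 with an estimated correlation). Among them stood Ccn2 at -1.53 (SE 0.28, adjusted p = 0.193), the phosphatase Dusp1 at -1.32 (SE 0.26, adjusted p = 0.231) and the AP-1 subunit Fos at -1.22 (SE 0.26, adjusted p = 0.336), none passing singly. Sarcomere genes had a median of -0.31 (35 of 39 below 0, adjusted p = 1.08e-04; 0.414 with an estimated correlation), and DNA replication genes 0.15 (26 of 32 above 0, adjusted p = 0.022; 0.414 with an estimated correlation). Cholesterol biosynthesis had 0.31 (15 of 18 above 0, adjusted p = 0.0114; 0.293 with an estimated correlation) and interferon response 0.24 (13 of 19 above 0, adjusted p = 0.0333; 0.293 with an estimated correlation). An unadjusted p under 0.05 was met by 365 genes against 517 by chance, and 32.7% had non-overlapping arrays against 33.3% by chance. With the spread pooled over the DM arrays as well, a count under 517 does not show that effects were absent. Gsta1 differed by -2.21 and -2.70 within the first and second chips, 4 genes passed with the BeadChip as a fixed block and 0 with median scaling, and Gsta1 was 2.93 higher against DM. Its call also rested on single arrays, with values from -2.82 to -2.08 and adjusted p = 0.992 without siBAF60b replicate 1, 0.265 without siBAF60b replicate 2, 0.0614 without siScramble replicate 1 and 0.22 without siScramble replicate 2. It did not pass with every probe tested (adjusted p = 0.0833), with only the groups compared (adjusted p = 0.136) or without any 1 array of GM or siBRG1. Within the first and second chips the sarcomere median was -0.39 and -0.27 and the immediate early median -0.51 and -0.35. Against DM the immediate early median turned to 0.55, and the immediate early list alone passed without siScramble replicate 1. The sarcomere list (adjusted p = 0.504), DNA replication (adjusted p = 0.504), cholesterol biosynthesis (adjusted p = 0.162) and interferon response (adjusted p = 0.251) did not. Without siBAF60b replicate 2 the sarcomere list (adjusted p = 0.157), DNA replication (adjusted p = 0.0827) and interferon response (adjusted p = 0.328) did not pass.

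In siBAF60c cells 1 gene rose, the alpha-globin gene Hba-a1 (2.09 on the log2 scale in siBAF60c against siScramble, SE 0.27, adjusted p = 0.02, 2 arrays per group). Ccnd1 stood 1.05 higher without passing (SE 0.27, adjusted p = 0.459). Ckm at -0.96 (SE 0.43), Tnnt3 at -0.79 (SE 0.37), Myog at -0.78 (SE 0.52), Cdkn1a at -0.39, Chrna1 at -0.04, Myod1 at 0.18 and Mef2c at 0.25 did not pass either (adjusted p = 1.00 for each). Muscle energy metabolism was lower (median -0.55, 13 of 16 below 0, adjusted p = 3.50e-06; 0.279 with an estimated correlation), with Mb at -0.90 (adjusted p = 0.817). Sarcomere genes had a median of -0.42 (33 of 39 below 0, adjusted p = 1.65e-08; 0.371 with an estimated correlation), with Acta1 at -1.26 (SE 0.34, adjusted p = 0.565). Excitation-contraction coupling had -0.35 (14 of 18 below 0, adjusted p = 0.00242; 0.371 with an estimated correlation). The unfolded protein response had 0.13 (14 of 22 above 0, adjusted p = 0.039; 0.371 with an estimated correlation), with the stress-induced gene Chac1 at 0.90. Neuronal markers passed upward with a mean of 0.43 while their median was 0.02 (2 of 9 rose over the list alone, adjusted p = 0.0104; 0.371 with an estimated correlation). That list rests on few genes such as Nefm (at least 2.41-fold higher, adjusted p = 0.101) and the growth cone gene Gap43 (1.35, adjusted p = 0.339). An unadjusted p under 0.05 was met by 477 genes against 517 by chance, and 32.6% had non-overlapping arrays. The pooled spread limits this count too. Hba-a1 differed by 2.33 and 1.86 within the first and second chips, 2 genes passed with the BeadChip as a fixed block and 0 with median scaling. Its call also rested on single arrays, with values from 1.97 to 2.23 and adjusted p = 0.303 without siBAF60c replicate 1, 0.105 without siBAF60c replicate 2, 0.355 without siScramble replicate 1 and 0.185 without siScramble replicate 2. It did not pass with every probe tested (adjusted p = 0.0578), with only the groups compared (adjusted p = 0.226), without GM replicate 2 or without either siBAF60b array. Within the first and second chips the median was -0.22 and -0.73 for sarcomere, -0.21 and -0.46 for excitation-contraction coupling, and -0.77 and -0.51 for energy metabolism. Without siBAF60c replicate 2 the sarcomere list (-0.03, adjusted p = 0.926), excitation-contraction coupling (-0.06, adjusted p = 0.926), energy metabolism (-0.35, adjusted p = 0.136) and the unfolded protein response (0.05, adjusted p = 0.926) did not pass.

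Compared directly, siBAF60c and siBRG1 differed in 12 genes, 9 higher and 3 lower in siBAF60c. Higher were the chemokine Cxcl13 (2.81 on the log2 scale, SE 0.32, adjusted p = 0.00378), Ly6c1 (2.96, SE 0.51, adjusted p = 0.0443), Depp1 (1.97, SE 0.30, adjusted p = 0.023) and the glutathione transferase Gstm2 (1.92, SE 0.25, adjusted p = 0.0119). Lower were the sphingosine kinase Sphk1 (-1.95, SE 0.28), the mitochondrial gene Mgarp (-1.80, SE 0.29) and Crabp1 (at least 2.09-fold). DNA replication genes were lower in siBAF60c (median -0.54, 32 of 32 below 0, adjusted p = 3.83e-11; 0.194 with an estimated correlation). So were mitosis (-0.27, 26 of 26 below 0, adjusted p = 0.00532; 0.382 with an estimated correlation) and interferon response genes (-0.33, adjusted p = 0.00696; 0.194 with an estimated correlation). Fusion genes (0.36; 0.21 with an estimated correlation), the dystrophin complex (0.34; 0.21), sarcomere (0.19; 0.508) and neuronal markers (0.13; 0.21) were higher, each with adjusted p = 0.00696 at the preset correlation. Excitation-contraction coupling was higher too (0.31, adjusted p = 0.0347; 0.43 with an estimated correlation). Within the first chip Cxcl13 differed by 2.84 and the sarcomere and replication medians were 0.55 and -0.63. With the BeadChip as a fixed block Ly6c1 (2.47, adjusted p = 0.0912) and Crabp1 (adjusted p = 0.0807) did not pass. None of the 12 genes (0) passed when any 1 array of siBRG1 or siBAF60c was left out, and 0 with median scaling. That scaling shifted the all-gene median by -0.33, and the sarcomere, coupling, fusion and dystrophin medians then stood above it at -0.11, -0.08, -0.08 and -0.04. Without background correction 24 genes passed, 13 of them higher (54.2% against 75%), and the sarcomere median turned to -0.20 without siBAF60c replicate 1, when DNA replication alone of the 8 lists passed.

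Between siBAF60b and siBRG1 9 genes differed, 6 higher and 3 lower in siBAF60b. The hormone gene Stc1 (1.95 on the log2 scale, SE 0.27, adjusted p = 0.0385), the secreted factor Ecrg4 (at least 3.14-fold), the vasopressin receptor Avpr1a (1.89, SE 0.32, adjusted p = 0.0473; a second probe 0.17) and the glutathione transferase Mgst2 (1.80, SE 0.30) were higher. Sema7a (-1.93, SE 0.31), Nefm (at least 2.64-fold; a second probe -0.73) and Crabp1 (at least 2.21-fold) were lower. Sarcomere (0.45, adjusted p = 2.46e-07; 0.236 with an estimated correlation) and excitation-contraction coupling genes (0.46, adjusted p = 7.52e-05; 0.194 with an estimated correlation) were higher in siBAF60b. The dystrophin complex (0.48, adjusted p = 7.52e-05; 0.0986 with an estimated correlation) and energy metabolism genes (0.35, adjusted p = 0.00157; 0.194 with an estimated correlation) were higher too. So were cell cycle exit (0.16, adjusted p = 0.035; 0.194 with an estimated correlation) and cholesterol biosynthesis genes (0.16, adjusted p = 0.0249; 0.207 with an estimated correlation). DNA replication (-0.40, 30 of 32 below 0, adjusted p = 8.23e-09; 0.135 with an estimated correlation) and immediate early genes (-0.50, 8 fell over the list alone, adjusted p = 1.85e-10; 0.0857 with an estimated correlation) were lower. Within the first chip Stc1 differed by 1.89, Sema7a by -2.11, and the sarcomere and replication medians were 0.45 and -0.38. However, 0 genes passed with the BeadChip as a fixed block, with median scaling, or when any 1 array of siBRG1, siBAF60b or siScramble was left out, and the count ran from 0 to 47 over all arrays left out and was 177 with array weights. That scaling shifted the all-gene median by -0.15, and the cell cycle exit and cholesterol medians then stood above it at -0.03 and -0.02.

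No gene separated siBAF60c from siBAF60b in limma (0 of 10346), and 514 had an unadjusted p under 0.05 against 517 by chance. With the replicate number as a block 3 genes passed, with the BeadChip as a random block 11 and with array weights 26. The genes with the smallest p were the matrix gene Dpt (at least 4.17-fold lower in siBAF60c), Igsf5 (1.73 on the log2 scale; a second probe -0.10) and the calcium-binding gene S100a3 (1.78, detected on 1 siBAF60b array), each with adjusted p = 0.0508. Immediate early genes were higher in siBAF60c than in siBAF60b (median 0.35, 21 of 24 above 0, adjusted p = 5.83e-06; 0.183 with an estimated correlation), with Ccn2 at 1.67 (adjusted p = 0.0636) and the stress factor Atf3 at 1.71 (adjusted p = 0.0764). Neuronal markers were higher as well (0.26, adjusted p = 0.0193; 0.219 with an estimated correlation). Cholesterol biosynthesis (-0.31, 17 of 18 below 0, adjusted p = 7.75e-04; 0.183 with an estimated correlation) and energy metabolism genes (-0.16, adjusted p = 0.0193; 0.333 with an estimated correlation) were lower.

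Only 1 gene was called in siBAF60b and 1 in siBAF60c, so no pair of knockdowns could share more than 1. The small numbers shared therefore do not show that the knockdowns differed. Hba-a1 rose in both siBRG1 and siBAF60c, and Gsta1 fell in both siBRG1 and siBAF60b, while 0 genes were shared between siBAF60b and siBAF60c. Against the mean of siBAF60b and siBAF60c, Gsta1 in siBRG1 stood at only -1.21, less far than against siScramble. Gsta1 thus also lay below siScramble in siBAF60c, without passing, and its fall was not particular to siBRG1 and siBAF60b. Without effects, the simulated data shared 0 genes at the same threshold. Hardly any gene is expected to be called there without effects, so that 0 does not test the sharing. Changes against the common siScramble arrays correlated at r 0.471 for siBRG1 and siBAF60c, 0.519 for siBRG1 and siBAF60b, and 0.455 for siBAF60b and siBAF60c, where the shared control alone gave 0.50 in simulation. The covariance exceeded the simulated one by 0.0106 and 0.0115 and stood -0.00537 from it in the last pair. At an unadjusted p under 0.05, siBRG1 and siBAF60c shared 66 higher and 108 lower genes, where independent lists would give 8.77 and 10.5 and the shared control 53.2 and 52.5. For siBRG1 and siBAF60b the numbers were 50 and 82, against 6.34 and 8.38 for independent lists and 54.3 and 52.9 from the shared control, and for siBAF60b and siBAF60c 32 and 69, against 3.29 and 5.23 and 53.8 and 52.2. The simulated data held no effects and gave a gene the same spread in every group, so their 0.50 follows from sharing 1 control. Their covariance depends on that pooled spread, which includes the DM arrays. Their lists were shorter than those of siBRG1, and no excess over sharing is claimed.

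Cells given the scrambled siRNA differed from wild-type cells in the same medium. The genes Prl2c2 and Prl2c3 stood at least 66.8-fold and 76.7-fold higher in siScramble than in DM (adjusted p = 1.15e-06 for Prl2c2), and Prl2c4 rose by 5.73 (SE 0.46) and Gsta2 by 5.40 (SE 0.46), both from detection on 1 DM array. The Notch-regulated gene Nrarp (-2.75, SE 0.30), the synaptic organizer Cbln1 (-2.64, SE 0.28), the muscle myosin Myo18b (-2.60, SE 0.32) and the growth factor receptor Pdgfrb (-2.57, SE 0.43) fell. Pdgfrb did not pass with median scaling (adjusted p = 0.075), with only the groups compared (adjusted p = 0.111) or without siScramble replicate 2 (adjusted p = 0.062). Immediate early genes were higher in siScramble (median 1.28, 12 of 24 rose, 14 and 1 fell over the list alone, adjusted p = 1.40e-12; 0.054 with an estimated correlation). Among them stood Fos at 3.81 (SE 0.26, adjusted p = 1.39e-06) and Phlda1 at 3.01. Mitosis genes were higher as well (0.67, 3 of 26 rose, 9 over the list alone, adjusted p = 1.33e-07; 0.224 with an estimated correlation), with Cdk1 at 1.61 (SE 0.39, adjusted p = 0.0396). Neuronal markers were higher too (0.27, 3 of 9 rose, adjusted p = 0.0149; 0.224 with an estimated correlation), with the microtubule gene Map2 at 1.99 (SE 0.30). Of the differentiation genes Myog (-1.13, adjusted p = 0.261), Ckm (-0.78, adjusted p = 0.344), Tnnt3 (-0.74, adjusted p = 0.3), Chrna1 (-0.51), Myod1 (-0.11), Mef2c (-0.08), Cdkn1a (0.05) and Ccnd1 (0.49) did not pass. Of the 10346 genes 352 passed (172 higher, 180 lower). Within the second chip Prl2c2 differed by 7.22 and the immediate early and mitosis medians were 1.09 and 0.92. With median scaling 23 passed (16 higher, 69.6% against 48.9%), without DM replicate 1 2279 and without siScramble replicate 2 114. With the BeadChip as a fixed block 9 lists passed instead of 3, among them sarcomere (-0.30, adjusted p = 0.0016).

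**Figure D4:**
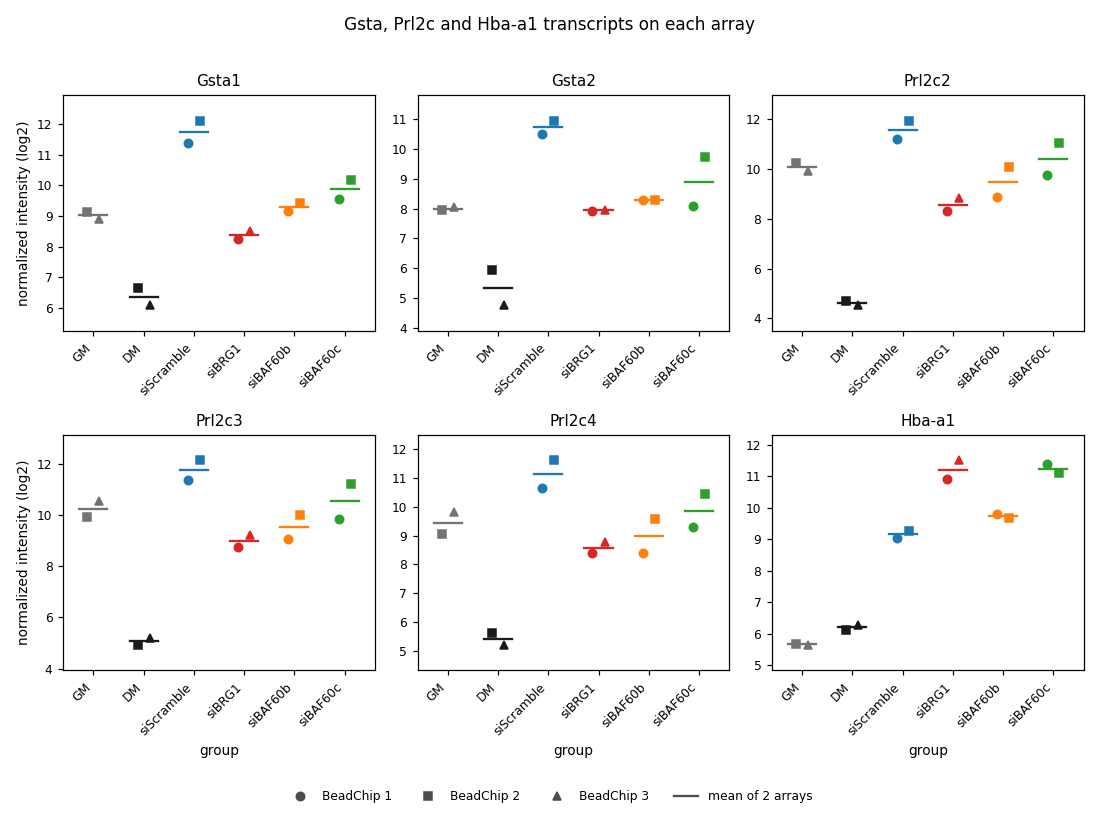
Each point is 1 array; Gsta1 differed from siScramble by -3.37 in siBRG1 and -2.45 in siBAF60b, and Hba-a1 by 2.06 in siBRG1 and 2.09 in siBAF60c. Lines are means of 2 arrays.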

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

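The differentiation-medium replicates differed from each other more than those of any other group (r 0.945; 1836 genes apart by more than 1 on the log2 scale). Of the tests, that of a dim array was stated before its result was seen, and the tests of a wrong label, the BeadChip and further differentiation were chosen after. A wrong label of replicate 2 was not supported, since it correlated more closely with replicate 1 than with the closest array of another group by 0.015. That test does not cover replicate 1, whose median r with the transfected arrays was 0.967, above its 0.945 with replicate 2. The BeadChip was not supported, since the deviation of replicate 2 correlated with those of the other arrays of the chip at no more than 0.058. A dim array was not supported either, since among the brightest genes the difference between the replicates was 2.18 times that of the next widest group (0.53 against 0.243). Further differentiation in replicate 2 remained open: genes higher in siScramble than GM stood 0.279 higher in replicate 2, but the genes lower in siScramble than GM stood 0.138 higher as well, and all genes 0.154.

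Sarcomere genes stood at -0.76 in siBRG1, which passed at the preset correlation but not with an estimated correlation (adjusted p = 0.0888), and of the tests that of quantile normalization was stated before its result was seen and the others after. The BeadChip did not account for it, since within the chip that held both groups the sarcomere median was -0.931. With median scaling the sarcomere median was -0.49, or -0.81 relative to an all-gene median of 0.32. Its sign therefore did not rest on quantile normalization. How far its size did is not shown, since the -0.81 again removes the shift of all genes. Unusual siScramble arrays did not account for all of the sarcomere difference, since against the mean of siBAF60b and siBAF60c the median was still -0.376 (adjusted p = 1.28e-05; 0.285 with an estimated correlation). Reduced differentiation as a whole remained open: 8 of the 11 lists that passed between DM and GM had the opposite sign in siBRG1, while SRF targets (-0.13), cholesterol biosynthesis (0.07) and TGF-beta targets (-0.15) did not. It is not known from these arrays whether BRG1 acts on these genes directly.

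The Gsta and Prl2c genes were among the largest falls in siBRG1 and among the largest rises of siScramble over DM, and the test of transfection-raised genes was stated before its result was seen and the others after. Unusual siScramble arrays did not account for the whole difference, since against the mean of siBAF60b and siBAF60c the median of the 5 genes was still -1.044, but it was -2.796 against siScramble, so more of it disappeared than remained. A single transcript read by several probes remained open, since the members of a family differed by at most 1.017 standard errors. A general loss of transfection-raised genes in siBRG1 remained open as well, with the 60 genes higher in both siBAF60b and siBAF60c than in DM at a median of -0.197, and 38 of them below 0. The scrambled siRNA may itself have raised these genes, and a second control siRNA would separate that from an effect of BRG1.

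In direct comparisons, planned before the data were examined, 12 genes differed between siBRG1 and siBAF60c and 9 between siBRG1 and siBAF60b. Both counts were 0 with median scaling and when any 1 array of the 2 groups compared was left out, and the second was also 0 with the BeadChip as a fixed block. Probes without a gene name were followed as well. Of 2439 such probes, 242 changed between DM and GM (94 higher by up to 5.92 and 148 lower by up to -5.50), 25 between siScramble and DM (16 higher by up to 4.66 and 9 lower by up to -2.49) and 3 between siBRG1 and siScramble (1 higher by 2.28 and 2 lower by up to -2.66). Their genes are not given in the sources used here.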

How the results depend on the processing

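All settings below were fixed before the data were examined except the fit of the 8 transfected arrays alone, which was chosen after seeing the data. For the settings that changed a count, the cause was not tested. Of the named genes called, 763 values under the other settings kept their call, 120 lost it and 26 moved, and with 1 array left out 514 kept it and 218 lost it. Of the lists that passed, 723 values kept the call and 19 lost it, and with 1 array left out 600 kept it, 47 lost it and 1 turned. With fry 18 lists passed between DM and GM, 9 in siBRG1, 2 in siBAF60b, 1 in siBAF60c and 9 between siScramble and DM. Between siBAF60c and siBAF60b 4 passed fry, between siBAF60c and siBRG1 4 and between siBAF60b and siBRG1 5. The sarcomere list passed fry between DM and GM but in no knockdown against siScramble. In siBRG1 the excitation-contraction coupling, energy metabolism and DNA replication lists passed fry. With an estimated correlation for lists 0 lists passed in each of the 8 comparisons, and the differentiation-induced genes stood at -0.24 in siBRG1 (p = 0.143), -0.0711 in siBAF60b (p = 0.616) and -0.12 in siBAF60c (p = 0.329) with that correlation, p not adjusted.

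Without background correction 2 genes passed in siBAF60b, 2 in siBAF60c, 24 between siBAF60c and siBRG1 and 2 between siBAF60b and siBRG1, and 7 lists passed between siScramble and DM. With the authors' processed values the numbers were 2 in siBAF60b, 2 in siBAF60c, 3 between siBAF60c and siBAF60b and 25 between siBAF60c and siBRG1, with 7 lists between siScramble and DM. With median scaling in place of quantile normalization 0 genes passed in siBRG1, siBAF60b, siBAF60c, siBAF60c against siBRG1 and siBAF60b against siBRG1, and 23 between siScramble and DM, with 5 lists there. No gene was then shared by siBRG1 and siBAF60c (0) or by siBRG1 and siBAF60b (0), and the differentiation-induced genes in siBAF60b turned to 0.0302. Median scaling also turned Smarca4 (-0.0332), Smarcd2 (-0.39) and Smarca2 (-0.25) between DM and GM, and Smarca4 (0.0209), Smarca2 (0.20), Myog (0.18) and Ccnd1 (0.0687) in siBAF60b, none of which had passed. Its shift of the all-gene median between DM and GM was -0.48, in siBRG1 0.32 and in siBAF60b 0.17, so these turns lie in the direction of that shift.

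With no filter on dim probes 2 genes passed in siBAF60c, 3 between siBAF60c and siBAF60b and 20 between siBAF60c and siBRG1. With every kept probe tested 0 passed in siBAF60b, 0 in siBAF60c and 3 between siBAF60b and siBRG1, with 0 shared by siBRG1 and siBAF60c, 0 by siBRG1 and siBAF60b, and 6 lists between siScramble and DM. With the mean of the probes of a gene 2 passed in siBAF60c and 22 between siBAF60c and siBRG1, and values near 0 turned for Smarca2 in siBRG1 (-0.18), siBAF60b (0.0921) and siBAF60c (-0.14), Myog in siBAF60b (0.0441) and Chrna1 in siBAF60c (0.0865).

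With only 2 replicate numbers, pairs could not be established. Deviations from the group means correlated between same-numbered arrays at r 0.119 to 0.328 within the 4 transfected groups and at -0.039 to 0.328 over all 6. All 12 of 12 arrays deviated most like an array of their own number, but the 2 arrays of a group mirror each other. Replicate number and BeadChip partly coincide. Among siScramble, siBAF60b and siBAF60c, which shared both chips, r was 0.254 to 0.328, and for siBRG1 with these 0.119 to 0.137. GM and siBRG1, which shared the third chip, correlated at 0.322, but GM and DM, which shared both chips, at 0.058. With the replicate number as a block 2216 genes passed between DM and GM, 34 in siBRG1, 3 in siBAF60b, 1 in siBAF60c, 445 between siScramble and DM, 3 between siBAF60c and siBAF60b, 15 between siBAF60c and siBRG1 and 16 between siBAF60b and siBRG1, and 2 were shared by siBRG1 and siBAF60b. Lce1f in siBRG1 did not pass with that block (adjusted p = 0.0543). With the BeadChip as a fixed block 4 passed in siBAF60b, 2 in siBAF60c and 0 between siBAF60b and siBRG1. The shared genes were then 2 for siBRG1 and siBAF60c, 3 for siBRG1 and siBAF60b and 1 for siBAF60b and siBAF60c, and 9 lists passed between siScramble and DM. With the BeadChip as a random block 46 passed in siBRG1, 5 in siBAF60c, 11 between siBAF60c and siBAF60b, 31 between siBAF60c and siBRG1 and 16 between siBAF60b and siBRG1, with 3 shared by siBRG1 and siBAF60c and 1 by siBAF60b and siBAF60c.

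With an intensity trend and robust variance 3 genes passed in siBAF60c, 3 between siBAF60c and siBAF60b and 29 between siBAF60c and siBRG1, with 2 shared by siBRG1 and siBAF60c and 1 by siBAF60b and siBAF60c. With array weights 947 passed between DM and GM, 133 in siBRG1, 6 in siBAF60b, 5 in siBAF60c, 77 between siScramble and DM, 26 between siBAF60c and siBAF60b, 93 between siBAF60c and siBRG1 and 177 between siBAF60b and siBRG1. The shared genes were then 3 for siBRG1 and siBAF60c, 4 for siBRG1 and siBAF60b and 1 for siBAF60b and siBAF60c. With only the groups compared 730 passed between DM and GM, 0 in siBAF60b, 0 in siBAF60c, 36 between siScramble and DM, 2 between siBAF60c and siBAF60b and 29 between siBAF60b and siBRG1, with 0 shared by siBRG1 and siBAF60c and 2 by siBRG1 and siBAF60b. With the 8 transfected arrays alone 45 passed in siBRG1, 0 in siBAF60b, 2 in siBAF60c, 2 between siBAF60c and siBAF60b, 27 between siBAF60c and siBRG1 and 14 between siBAF60b and siBRG1, with 0 shared by siBRG1 and siBAF60b.

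With wild-type DM as the control 700 genes passed in siBRG1, 357 in siBAF60b and 521 in siBAF60c, and 9 lists in siBAF60b and 8 in siBAF60c. The differentiation-induced genes share the DM arrays with that control. The targets then passed over all genes, with Smarca4 at -1.83 in siBRG1, Smarcd2 at -1.99 in siBAF60b and Smarcd3 at -1.36 in siBAF60c. With DM as the control of the second knockdown 5 genes were shared by siBRG1 and siBAF60c and 2 by siBRG1 and siBAF60b, and with DM as the control of the first 0 by siBRG1 and siBAF60b and 1 by siBAF60b and siBAF60c. The direction turned for genes that the transfected groups held above DM: in siBRG1 Gsta1 (2.02), Gsta2 (2.60), Prl2c2 (3.95), Prl2c3 (3.93), Prl2c4 (3.17), Ly6c1 (1.41) and Depp1 (0.78), and in siBAF60b Gsta1 (2.93). Of these, Ly6c1 and Depp1 did not pass against DM. It also turned for the immediate early list in siBAF60b (0.55), Ccnd1 in siBAF60b (0.32), Smarcd2 (-0.41) and Smarca2 (-0.58) in siBRG1, and Smarca2 in siBAF60c (-0.62).

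With each array left out in turn, a group of 1 array being assumed to vary like the others, the genes passing ran from 920 (without GM replicate 2) to 3447 (without DM replicate 1) between DM and GM, from 1 to 67 in siBRG1, from 0 to 2 in siBAF60b, from 0 to 3 in siBAF60c and from 114 (without siScramble replicate 2) to 2279 (without DM replicate 1) between siScramble and DM. They ran from 0 to 12 between siBAF60c and siBAF60b, from 0 to 58 between siBAF60c and siBRG1 and from 0 to 47 between siBAF60b and siBRG1. Shared genes ran from 0 to 1 for siBRG1 and siBAF60c, from 0 to 2 for siBRG1 and siBAF60b, and were 0 throughout for siBAF60b and siBAF60c. Lists passing ran from 9 to 13 between DM and GM, from 8 to 10 in siBRG1, from 1 to 9 in siBAF60b, from 1 to 6 in siBAF60c and from 2 to 6 between siScramble and DM. They ran from 2 to 7 between siBAF60c and siBAF60b, from 1 to 9 between siBAF60c and siBRG1 and from 6 to 9 between siBAF60b and siBRG1. The differentiation-induced genes ran from -0.32 to -0.12 in siBRG1, from -0.13 to -0.026 (without siScramble replicate 1) in siBAF60b and from -0.18 to -0.0566 (without siBAF60c replicate 2) in siBAF60c.

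Some values of genes that had not passed turned with 1 array left out, and their lowest and highest values follow. Between DM and GM, Smarcd2 ran from -0.0944 (without DM replicate 2) to 0.97 and Myod1 from -1.20 to 0.24 (without DM replicate 2). In siBRG1, Mef2c ran from -0.0942 (without siScramble replicate 1) to 0.64, Ccnd1 from -0.0325 (without siScramble replicate 1) to 0.32 and Smarcd2 from -0.28 (without siBRG1 replicate 1) to 0.32. In siBAF60b, Smarca4 ran from -0.65 to 0.29 (without siBAF60b replicate 2), Smarcd3 from -0.58 to 0.0094 (without siScramble replicate 1), Smarca2 from -0.17 to 0.15 (without siBAF60b replicate 1) and Myog from -0.53 to 0.47 (without siScramble replicate 1). In siBAF60c, Smarca4 ran from -0.52 to 0.052 (without siScramble replicate 1), Smarca2 from -0.0227 (without siBAF60c replicate 2) to 0.24, Myog from -1.66 to 0.0896 (without siBAF60c replicate 2), Mef2c from -0.11 (without siScramble replicate 1) to 0.62 and Chrna1 from -0.28 to 0.21 (without siScramble replicate 2). The sarcomere list between siBAF60c and siBRG1, which had passed, ran from -0.20 (without siBAF60c replicate 1) to 0.77.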

Other observations

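The tests in this part were planned before the data were examined, and the choice of results was made after they were seen. The Smarcd3 transcript rose with differentiation (1.31, SE 0.35, adjusted p = 0.0162), while Smarca4 stood at 0.74 and Smarcd2 at 0.44 without passing, and whether the 3 subunits differ in this was not tested. The rise did not pass without DM replicate 2 (0.79), without either GM array, with median scaling (0.54), with array weights or with only the groups compared. In siBRG1 the sarcomere list stood at -0.76 and the replication list at 0.51, with adjusted p = 0.0888 and 0.0625 with an estimated correlation. In siBAF60c the sarcomere and energy lists stood at -0.42 and -0.55 (adjusted p = 0.371 and 0.279 with an estimated correlation). The energy list did not separate siBAF60c from siBRG1 (adjusted p = 0.542), and the sarcomere difference between them, 0.19, turned to -0.20 without siBAF60c replicate 1.

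A difference between BAF60c and BAF60b was not established. With the fit as reported 0 genes separated the 2 knockdowns, against 11 with the BeadChip as a random block and 26 with array weights. The count was 3 with the replicate number as a block, with the authors' values or with a trended robust variance. Immediate early genes stood 0.35 higher in siBAF60c (adjusted p = 5.83e-06; 0.183 with an estimated correlation), and 3 further lists passed only at the preset correlation. The sarcomere list in siBAF60c was -0.03 without siBAF60c replicate 2. The transcripts were lowered to different degrees (52.3% and 34.1% of siScramble). With Smarcd3 at 52.3% of control, how much of the protein and its function remained is not known from these arrays. Protein was not analysed here.

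Much of what the knockdowns had in common may come from the shared siScramble arrays. The correlations between knockdowns were 0.471, 0.519 and 0.455. The simulation held no effects and the same spread in every group, so its 0.50 follows from sharing 1 control. With DM as the control of 1 of the 2 knockdowns the correlations ran from 0.0243 to 0.136. That change of control also brings in the differences between siScramble and DM. These values therefore do not show how much came from the shared arrays. The Gsta and Prl2c genes of siBRG1 stood at -2.796 against siScramble but -1.044 against the other knockdowns. Part of their fall could reflect siScramble arrays that were high in these genes. A fall shared by the other knockdowns would give the same values, and these arrays do not tell the 2 apart.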
